A study of Homo sapiens with 10 samples.

How the data were processed

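Gene expression was measured on Affymetrix arrays in 10 tumours of LuCaP35, a human prostate cancer grown under the skin of NOD/SCID mice, which lack a working adaptive immune system. They formed 2 groups, 5 control and 5 castration tumours. Tumours had grown for about 1 month, and castration tumours were harvested 4 weeks after surgical castration, per the labels. The treatment protocol names a sham operation, while the labels of the controls and the design text call them untreated and give no time of harvest, so whether the controls had surgery is not settled by these sources. Labelled RNA was prepared from 6 ug of total RNA per tumour. The design text speaks of xenografts from mice without stating that every tumour came from a mouse of its own, so the p-values measure the spread between these 10 tumours. Replicates were numbered in the order of the records, and the numbers pair nothing.

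The values are linear signal intensity per probe set, deposited by the authors and made with MAS5, per the submitters' processing notes. Every array had a 2% trimmed mean of 500, which is the global scaling of MAS5, and no further normalization between arrays was seen in the values. The array platform, the genome build and detection calls are not given in the sources used here, so no coordinates are printed. A second table holds the authors' comparison of the groups for each probe set: p-values and q-values, group mean intensity, the ratio or fold of the means, and a t score, per the file headers. In the authors' deposited table the control mean lay within 1% of the arithmetic mean of the deposited signals for 53077 of 54675 probe sets (97.1%), and its p-values differed from those of a Welch calculation on the unlogged signals by a median of 0.000749 in log10.

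Gene symbols came from the authors' deposited table. Of 54675 probe sets, 40040 had 1 gene symbol, 1488 had several and 13147 had none. Of those with 1 symbol, 31810 symbols were current in the NCBI RefSeq gene table of assembly GRCh38.p14, 5163 older symbols were updated through it and 3067 were kept as given, among them symbols that are synonyms of more than 1 gene and symbols that a spreadsheet had turned into dates. CDK1 is one such case: its probe sets carry the older symbol CDC2, which the table pairs with more than 1 gene, so the proliferation list was measured without it. 62 control probe sets were left out of the tests, as were 52 probe sets of chromosome Y genes or XIST. Probe sets with several symbols or none were not named.

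Signals were analysed as log2(signal + 16), so fold changes are on that scale and understate changes of dim genes. Each gene was represented by its probe set with the highest mean, and genes whose mean was below the median of all non-control probe sets (7.05 on the log2 scale) were left out, which left 12940 of 19671 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, 12.8 degrees of freedom), and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have changed. SE is the moderated standard error of the log2 change, and SD is over the 5 tumours of a group. The number of arrays limits the precision. On data simulated from these arrays with 200 genes changed among 12940, 42% of genes changed 1.5-fold, 92% of those changed 2-fold and 96% of those changed 4-fold were recovered, and 2.98% of the calls were of unchanged genes. The simulation drew genes independently and changed far fewer than the 4084 called in the data. Its shares therefore need not hold for the real comparison.

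27 gene lists were fixed before the data were examined, and 26 had at least 3 measured members. They cover androgen response, androgen synthesis, cell division, cell cycle inhibitors and apoptosis, mesenchymal, epithelial, neuroendocrine and basal or stem markers, lipid synthesis, protein folding, hypoxia, oxidative phosphorylation, interferon response, antigen presentation, steroid receptors, growth factor signalling, immediate early and heat shock genes, ribosomal proteins, and markers of host fibroblasts, endothelium, macrophages, lymphocytes, muscle, fat and red cells. The host markers are human probe sets, and mouse RNA binds them only in part. Lists were tested with camera, which compares the members of a list with the other genes (preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists). They were also tested with camera at an estimated correlation, and with fry, which asks whether the members of a list move on balance one way. A list score is the mean log2 value of the measured members per tumour. Scores were compared by an exact two-sided permutation test over all 252 assignments of the 10 tumours, in which 0.00794 is the smallest p possible. Settings that leave out tumours have fewer assignments, so their p-values are not on the same footing.

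Genes were named by a rule set before the data were examined: the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap and whose brighter group mean lay above the median of all probe sets; a fixed set with KLK3, TMPRSS2, FKBP5, CDH1, CDH2, VIM, ZEB1 and MKI67 whatever their result; and from each list up to 4 members with the smallest p, with any member that went against the list. Genes named outside this rule are marked as such, and the results of some genes that the rule chose are not reported. Alternatives covered the offset, the filter, the normalization between arrays, the probe set of a gene, the variance model, the test, the thresholds, the set test and leaving out each tumour in turn. Leaving out control 1 and castration 4 together, and a Welch calculation on the unlogged signals, were chosen after seeing the data, as was a repeat of the settings that change the offset or the tumours with the probe set of each gene kept. RNA quality was followed by the log2 ratio of the 3-prime to the 5-prime control probe sets of GAPDH and ACTB.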

Results

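The series asked how androgen deprivation changes gene expression in LuCaP35 prostate cancer xenografts. RNA of 5 tumours from control mice and 5 tumours from castrated mice was measured as MAS5 signal on 1 array each. Median signal per array ran from 109 to 145, with every array scaled to a trimmed mean of 500. The first principal component held 53.4% of the variance and separated the groups, from -36.9 to -11.1 in controls and from 12.1 to 42.0 after castration. Control 1 (-11.1) and castration 4 (12.1) lay nearest to the other group and apart from the remaining tumours on the second component (25.7 and 29.7, 12.02% of the variance). The 3-prime to 5-prime log2 ratio of the control probe sets was 0.187 ± 0.058 (SD, n = 5) in controls and 0.223 ± 0.029 (SD, n = 5) after castration, a difference of 0.0355 (exact two-sided permutation p = 0.286).

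Castration was followed by changes in 4084 of the 12940 genes tested (31.6%), of which 2349 rose and 1735 fell. The change was at least 2-fold for 386 genes that rose and 316 that fell. Among the largest rises were FAM3D, a secreted cytokine-like protein, from a signal of 380 ± 122 to 9855 ± 5584 (SD, n = 5 per group, 20.8-fold), and F3, the tissue factor that starts coagulation, from 57.0 ± 69.3 to 1072 ± 138 (19.4-fold). The largest falls were in LEFTY1, a secreted antagonist of Nodal signalling, from 8035 ± 4322 to 264 ± 138 (22.4-fold lower), MYBPC1, a myosin-binding protein, from 2715 ± 1411 to 210 ± 329 (19.5-fold lower), and LAMA1, a laminin chain of basement membranes, from 7115 ± 2898 to 357 ± 157 (18.5-fold lower). Adjusted p in limma was 8.9e-05 for FAM3D, 4.6e-05 for F3, 0.000582 for LEFTY1, 0.00056 for MYBPC1 and 3.1e-05 for LAMA1. The size of 2 of these falls depended on 1 tumour: LEFTY1 was 38.5-fold lower without control 1 and MYBPC1 31.3-fold lower without castration 4. The control signals of F3 were near background in 4 of 5 tumours (10.6 to 40.5), so its fold depends on the offset (10.3-fold with an offset of 64, 30.1-fold without one).

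Among the other large rises, RGS2, which dampens G protein signalling, rose by 3.69 ± 0.42 (SE) on the log2 scale, and MYLK, the kinase of myosin light chain, by 3.51 ± 0.32. WNT5A, a non-canonical Wnt ligand, rose by 3.41 ± 0.39, JAG1, a Notch ligand, by 3.36 ± 0.46, and PTPRB, a receptor phosphatase, by 3.34 ± 0.58. GIMAP7, a GTPase of the immunity-associated family, rose by 3.72 ± 0.78 (4.48 without control 1), and SI, the intestinal sucrase-isomaltase, by 3.47 ± 0.27. The rises of GIMAP7 and SI and the fall of DEFB1 were smaller with an offset of 64 (2.82, 2.73 and -2.48). Among the falls, S100P, a calcium-binding protein, changed by -3.98 ± 0.64, the peptide hormone gene CCK by -3.23 ± 0.59, the defensin gene DEFB1 by -3.22 ± 0.54, LOC283352 by -3.04 ± 0.46 and the splicing regulator RBM20 by -2.84 ± 0.43. These genes were chosen among those whose groups did not overlap. The groups did not overlap for 19.03% of all genes tested, against 0.794% expected from chance. At an unadjusted p under 0.05, 5412 genes passed. The authors' comparison gave 4660 probe sets with a q-value under 0.05, 2710 higher and 1950 lower after castration. Of the 2277 of these that represented a tested gene, 2231 were also called here, and all 2231 had the same direction. A shared direction follows from the use of the same signals in both comparisons. The remaining genes of the 4084 called here did not reach that q-value. Among them were FAM3D (q-value 0.0816), LEFTY1 (0.0741) and MYBPC1 (0.0716), while F3 (0.00761) and LAMA1 (0.0475) reached it.

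**Figure D1:**
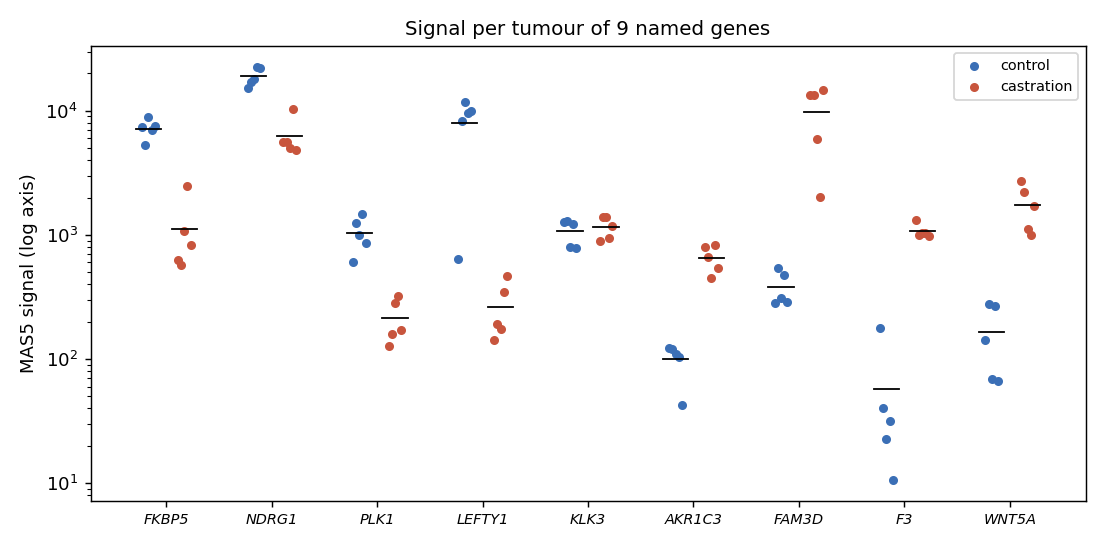
MAS5 signal (log axis) of 9 named genes in each tumour, with controls in blue, castration in red and the group mean as a black line. FKBP5 (7.33-fold), NDRG1 (3.11-fold), PLK1 (4.66-fold) and LEFTY1 (22.4-fold) were lower after castration, AKR1C3 (5.88-fold), FAM3D (20.8-fold), F3 (19.4-fold) and WNT5A (10.6-fold) were higher, and KLK3 overlapped between the groups.

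Genes that androgen induces in prostate cells fell in part. Of 32 measured members, 14 fell, 3 rose and 15 did not pass the test, with a median log2 change of -0.29. FKBP5, a co-chaperone of steroid receptors, fell from 7199 ± 1264 to 1117 ± 793 (SD, n = 5 per group, 7.33-fold lower, adjusted p = 0.00012). NDRG1 was 3.11-fold lower (adjusted p = 0.000142) and ACSL3, which activates fatty acids, 2.4-fold lower. KLK3, which encodes prostate-specific antigen, had signals of 1078 ± 263 and 1164 ± 240 (log2 change 0.12 ± 0.18 SE, adjusted p = 0.655), and neither of its 2 other probe sets passed. The KLK3 probe set used here carries a cross-hybridisation suffix, so its signal may include other transcripts. CAMKK2, a calmodulin-dependent kinase, rose by 0.56 ± 0.11, STEAP2, a metalloreductase, by 1.55 ± 0.40 and TMPRSS2, a surface protease, by 0.34 ± 0.12 (adjusted p = 0.0469). The call of TMPRSS2 ended without control 1, 2 or 4 or castration 2, 3, 4 or 5 (adjusted p from 0.0549 to 0.109), none of its 3 other probe sets passed, and averaging its probe sets gave 0.04. Averaging the probe sets of CAMKK2 gave 0.23 (adjusted p = 0.0689). The list shifted down in camera (adjusted p = 0.00265, but adjusted p = 0.396 with an estimated correlation), with 14 falls and 4 rises adjusted over the list alone. Its score was 10.6 ± 0.15 in controls and 10.1 ± 0.21 after castration (SD, n = 5, exact permutation p = 0.0159), and castration 4, at 10.5, was the highest of its group.

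Among 6 measured genes that androgen represses, 3 rose, 1 fell and 2 did not pass (median 0.36, camera adjusted p = 0.216). The list passed with fry (adjusted p = 0.000782) and by the exact permutation of its score (adjusted p = 0.0413). AKR1C3, an enzyme that makes testosterone from androstenedione, rose from 100 ± 33.0 to 654 ± 159 (5.88-fold, adjusted p = 5.5e-05). CAMK2N1, an inhibitor of CaM kinase II, rose 1.5-fold (adjusted p = 0.000654) and UGT2B15, which glucuronidates androgens, 1.68-fold (adjusted p = 0.0225). The call of UGT2B15 ended without castration 2 (adjusted p = 0.059) or castration 5 (adjusted p = 0.0557). HSD17B6 was the member that fell, against the list (3.76-fold lower, adjusted p = 0.0111). Both HSD17B6 and AKR1C3 are also counted in the list of androgen synthesis. MET, named outside the rule, had a change of 0.13 (adjusted p = 0.668). In the list of androgen synthesis and metabolism, 4 of 10 measured genes rose, 2 fell and 4 did not pass (median 0.45, camera adjusted p = 0.309, 6 rises and 2 falls adjusted over the list alone), and the list passed with fry (adjusted p = 0.0087) but not by the permutation of its score (adjusted p = 0.58). HSD17B4, a peroxisomal enzyme that inactivates steroids, rose from 4639 ± 309 to 10270 ± 1206 (2.2-fold, adjusted p = 2.6e-05). AKR1C3 rose as above, and the 5-alpha-reductase genes SRD5A1 (0.60, adjusted p = 0.0127) and SRD5A3 (0.53, adjusted p = 0.0276), named outside the rule, rose as well. DHRS9, a retinol dehydrogenase, fell 7.09-fold (adjusted p = 0.00034) and HSD17B6 3.76-fold (adjusted p = 0.0111).

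Genes of cell division fell together. Of 37 measured members of the proliferation list 35 fell and none rose, with a median log2 change of -0.93. The 2 that did not pass, MCM6 (-0.25, adjusted p = 0.451) and KIF2C (-0.33, adjusted p = 0.149), are named outside the rule. The mitotic kinase PLK1 went from 1035 ± 336 to 212 ± 85.2 (SD, n = 5 per group, 4.66-fold lower), cyclin A2 (CCNA2) was 2.64-fold lower, KIF20A, a kinesin of cytokinesis, 2.38-fold lower and BUB1B, a spindle checkpoint kinase, 1.66-fold lower, with adjusted p from 0.000216 to 0.00117. MKI67, the gene of the Ki-67 antigen, went from 672 ± 74.9 to 435 ± 87.5 (1.54-fold lower, adjusted p = 0.00596). The camera adjusted p was 4.2e-17, against an adjusted p = 0.396 with an estimated correlation. The score fell from 10.9 ± 0.16 to 9.97 ± 0.45 (exact permutation p = 0.00794), and every castration tumour lay below every control. Of 20 measured cell cycle inhibitors and apoptosis genes, 5 fell, 2 rose and 13 did not pass (median -0.05, camera adjusted p = 0.373). CDKN1A, which encodes p21, fell 7.01-fold from 564 ± 165 to 81.1 ± 73.6 (adjusted p = 0.000368), CDKN2A fell 1.87-fold, and FAS (-0.66, adjusted p = 0.0373) and RB1 (-0.34, adjusted p = 0.028), named outside the rule, fell as well. The pro-apoptotic BCL2L11 rose 1.44-fold and the stress gene GADD45A 1.59-fold. Averaging probe sets ended the call of BCL2L11 (adjusted p = 0.458), and that of GADD45A ended without control 4 or 5 or castration 1, 2 or 5 (adjusted p from 0.0515 to 0.066).

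Genes of cholesterol and fatty acid synthesis fell. In the cholesterol list 12 of 22 measured genes fell, 3 rose and 7 did not pass (median -0.46, camera adjusted p = 8.1e-05, adjusted p = 0.396 with an estimated correlation, 14 falls and 3 rises adjusted over the list alone). IDI1, which isomerises isopentenyl diphosphate, went from 4939 ± 633 to 2246 ± 809 (SD, n = 5 per group, 2.27-fold lower, adjusted p = 0.000753), with 1 other probe set of IDI1 called in the opposite direction (highest log2 change 0.46). TM7SF2 (0.86), PMVK (0.39) and SC5D (0.38), enzymes of the same pathway, rose. The call of PMVK ended without control 4 (adjusted p = 0.0519) and that of SC5D without castration 1 (adjusted p = 0.0607) or castration 2 (adjusted p = 0.0654), and averaging the probe sets of SC5D ended it as well (adjusted p = 0.0861). In the fatty acid list 8 of 15 measured genes fell, 1 rose and 6 did not pass (median -0.47, camera adjusted p = 0.000357, adjusted p = 0.293 with an estimated correlation). The desaturases FADS2 and SCD were 2.54-fold and 2.13-fold lower and the elongases ELOVL5 and ELOVL6 2.52-fold and 2.41-fold lower, with adjusted p from 8.9e-05 to 0.000219. ACACA, which makes malonyl-CoA, rose 1.53-fold (adjusted p = 0.000777). Castration 4 had the highest score of its group in both lists, 11.1 for cholesterol and 10.9 for fatty acids, where the others of its group were at most 10.7 in each.

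Hypoxia genes also fell, 14 of 21 measured with none that rose and 7 that did not pass (median -0.60, camera adjusted p = 3.4e-06, adjusted p = 0.402 with an estimated correlation, 15 falls adjusted over the list alone). Adrenomedullin (ADM) went from 1067 ± 529 to 191 ± 83.2 (SD, n = 5 per group, 5.02-fold lower, adjusted p = 0.000557), ANKRD37 was 2.69-fold lower, the glycolytic enzyme PGK1 1.56-fold lower and the oxygen sensor EGLN1 1.52-fold lower. In oxidative phosphorylation 13 of 29 measured genes rose, none fell and 16 did not pass (median 0.17, camera adjusted p = 0.0081, adjusted p = 0.437 with an estimated correlation, 15 rises and 1 fall adjusted over the list alone). ATP5PB, a subunit of ATP synthase, rose 1.38-fold, UQCRB of complex III 1.32-fold, NDUFB5 of complex I 1.33-fold and COX4I1 of complex IV 1.22-fold. The call of this list was lost after quantile normalization, where 9 members rose and 5 fell (median 0.10, camera adjusted p = 0.245). It also ended without both control 1 and castration 4 (camera adjusted p = 0.0579), where the median stayed at 0.17, with 11 members that rose and 1 that fell. Averaging probe sets ended the calls of UQCRB (adjusted p = 0.0519) and COX4I1 (adjusted p = 0.777).

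All 23 measured ribosomal protein genes rose, with a median log2 change of 0.40 (camera adjusted p = 8.8e-11, adjusted p = 0.396 with an estimated correlation). RPL8 went from 13512 ± 997 to 19501 ± 832 (SD, n = 5 per group, 1.44-fold), RPL13 rose 1.52-fold and RPS9 1.42-fold. These were among the brightest probe sets, and the rise depended on the scaling: after quantile normalization 8 of 23 rose, none fell and the median was 0.07 (camera adjusted p = 0.0172). With arrays centred on their median 22 of 23 rose (median 0.36).

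Mesenchymal and epithelial genes moved in both directions. Of 15 measured mesenchymal genes 6 rose, 2 fell and 7 did not pass (median 0.25, camera adjusted p = 0.398). TWIST1, a transcription factor of the mesenchyme, rose from 189 ± 32.1 to 372 ± 25.2 (1.91-fold, adjusted p = 0.00056), TCF4 rose 1.76-fold and the gelatinase MMP2 1.63-fold, and ZEB2 (1.27, adjusted p = 0.0147) and CDH11 (0.77, adjusted p = 0.0136), named outside the rule, rose as well. SNAI2, which encodes the repressor Slug, fell 9.65-fold from 1871 ± 1529 to 334 ± 488 (adjusted p = 0.0122) and LOX, a collagen cross-linking enzyme, 4.76-fold (adjusted p = 0.00207). The fall of SNAI2 was 16.2-fold without castration 4 and 6.13-fold without castration 5. LOX had 1 other probe set, which fell by 4.12 on the log2 scale. Vimentin (VIM) had signals of 1882 ± 828 and 4089 ± 2500 (2.02-fold higher, adjusted p = 0.0427), with overlapping groups, and its call ended without control 1, 2, 3 or 4 or castration 1, 2 or 5 (adjusted p from 0.062 to 0.0987) and on averaging its probe sets (adjusted p = 0.0865). CDH2 (N-cadherin, 43.7 ± 28.5 and 69.0 ± 31.8) and ZEB1 (29.5 ± 12.5 and 49.9 ± 13.2) lay below the filter, with adjusted p of 0.283 and 0.119 in a fit without it. The mesenchymal score differed by 0.04 (exact permutation p = 0.754), and by -0.52 when all probe sets of a gene were averaged (p = 0.00794). The score is a mean, to which large changes such as that of averaged LOX (-3.19) contribute most. The list median stayed positive in every setting that tested the list (lowest 0.0978), and camera called it in none (lowest adjusted p = 0.23). Without castration 2 the score differed by -0.16 (exact permutation p = 0.0397) when the probe set of each gene was chosen again. This exchanged the probe set of LOX. With the probe sets kept the score differed by -0.04 (exact permutation p = 0.508). Of 21 measured epithelial junction genes 4 fell, 2 rose and 15 did not pass (median -0.13, camera adjusted p = 0.147). ESRP2, an epithelial splicing regulator, fell 2.43-fold (adjusted p = 0.000457) and keratin 8 (KRT8) 1.59-fold (adjusted p = 0.00942), and CLDN3 (-0.38, adjusted p = 0.0171) and CLDN4 (-0.43, adjusted p = 0.0448) are the others, named outside the rule. RAB25, an epithelial trafficking GTPase, rose 2.04-fold (adjusted p = 8.5e-05) and OVOL2 1.81-fold. E-cadherin (CDH1) had signals of 12501 ± 2833 and 11173 ± 531 (log2 change -0.13 ± 0.14 SE, adjusted p = 0.536), while its other probe set fell by 0.99 and averaging both gave -0.56 (adjusted p = 0.0166). Without control 1 the change of CDH1 was -0.29 (adjusted p = 0.0123) and the list passed (camera adjusted p = 0.0267), as it did with averaged probe sets (0.0431). The epithelial score differed by -0.12 (exact permutation p = 0.111), but it passed without control 1 (-0.18, p = 0.00794), with the filter at the 75th percentile (-0.18, p = 0.0476), with averaged probe sets (-0.20, p = 0.0476) and without both control 1 and castration 4 (-0.17, p = 0.0286).

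In growth factor signalling 9 of 19 measured genes rose, 2 fell and 8 did not pass (median 0.38, camera adjusted p = 0.0903). The list passed with fry (adjusted p = 0.00145) and by the exact permutation of its score (adjusted p = 0.0295). The receptor ERBB4 rose from 119 ± 32.5 to 564 ± 141 (SD, n = 5 per group, 4.29-fold, adjusted p = 8.9e-05), ERBB2 rose 2.05-fold, the PI3-kinase subunit PIK3R3 2.28-fold and FGFR2 3.16-fold. IGF1R fell 1.49-fold (adjusted p = 0.00413) and the insulin receptor substrate IRS2 2.03-fold (adjusted p = 0.01). Averaging probe sets ended the calls of ERBB2 (adjusted p = 0.0782) and PIK3R3 (adjusted p = 0.093). Among 14 measured steroid receptors and cofactors 2 rose, 1 fell and 11 did not pass (median 0.07, camera adjusted p = 0.849). The mineralocorticoid receptor gene NR3C2 fell 4.07-fold (adjusted p = 0.000695), GATA2 rose 2.05-fold (adjusted p = 0.00551) and oestrogen receptor alpha (ESR1) 2.4-fold (adjusted p = 0.0287). The call of ESR1 ended without control 2, 3, 4 or 5 or castration 3 or 5 (adjusted p from 0.0564 to 0.0717). HOXB13 had a change of 0.26 (adjusted p = 0.0505) and passed without control 5 (adjusted p = 0.0471) or castration 3 (adjusted p = 0.0058).

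Among 4 measured neuroendocrine genes SCGN, which encodes secretagogin, rose 2.94-fold (adjusted p = 0.00655) and NCAM1 (0.03, adjusted p = 0.935), SNAP25 (-0.10, adjusted p = 0.653) and UCHL1 (-0.04, adjusted p = 0.887) did not pass. The median of that list was -0.01, its mean was 0.36 and its camera direction was up (adjusted p = 0.888). Of 9 basal and stem markers 3 rose and 2 fell (median 0.30, camera adjusted p = 0.992): BMI1 (0.53) and ITGA6 (0.56) were among those that rose, and KLF4 (-0.63) and ITGA2 (-0.46) fell. Averaging probe sets ended the call of ITGA2 (adjusted p = 0.0793). The call of ITGA6 ended without control 3, 4 or 5 or castration 1, 2 or 5 (adjusted p from 0.055 to 0.0797), and that of ITGA2 without control 1, 2 or 4 or castration 3, 4 or 5 (adjusted p from 0.0569 to 0.093).

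Of 24 genes of protein folding and endoplasmic reticulum stress 3 rose, 4 fell and 17 did not pass (median -0.07, camera adjusted p = 0.448). The transcription factor ATF4 (0.38) and the chaperone gene DNAJB9 (0.75) rose, the chaperone genes DNAJB11 (-0.65) and HYOU1 (-0.50) fell, and HERPUD1 (-0.54) and MANF (-0.37), named outside the rule, fell. DDIT3, which encodes CHOP, rose (0.39, adjusted p = 0.0488), but the call ended without control 1, 2, 3 or 4 or castration 1, 2, 4 or 5 (adjusted p from 0.0511 to 0.12), and after quantile normalization (adjusted p = 0.0725). Of 14 immediate early and heat shock genes 3 fell, namely HSPH1 (-0.74), HSPB1 (-0.61) and JUNB (-0.48), and 11 did not pass, among them KLF6 (-0.27, adjusted p = 0.125), with a median of -0.06 (camera adjusted p = 0.448). The call of HSPB1 ended without control 2, 4 or 5 or castration 1, 2 or 3 (adjusted p from 0.0511 to 0.0623), and that of JUNB without control 3 or 4 or castration 2 or 3 (adjusted p from 0.0515 to 0.0767).

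None of 32 measured interferon response genes passed in limma (median 0.13, camera adjusted p = 0.707). STAT2 had the smallest p (log2 change 0.45 ± 0.17 SE, adjusted p = 0.0566) and passed without castration 3 (adjusted p = 0.0113). IRF1 (0.36, adjusted p = 0.0754) passed without castration 3 (adjusted p = 0.00694) and with averaged probe sets (adjusted p = 0.0474), and IFIH1 (0.67, adjusted p = 0.09) passed without control 1 (adjusted p = 0.0482) or castration 3 (adjusted p = 0.0395). BST2 (0.40) had an adjusted p of 0.121. The interferon score was 11.2 in castration 4, against 8.89 to 9.90 in the other castration tumours and 8.97 to 10.01 in controls. Without both control 1 and castration 4 the list turned down (median -0.10, camera adjusted p = 0.602), with none that rose and 2 that fell. Of 12 antigen presentation genes B2M (0.26) and ERAP2 (0.65) rose and 10 did not pass (median -0.12, camera adjusted p = 0.888, none adjusted over the list alone). Without both control 1 and castration 4 none of the 12 rose and 6 fell (median -0.24, camera adjusted p = 0.198), and after quantile normalization none rose or fell. The call of B2M ended without castration 5 (adjusted p = 0.0547) after quantile normalization (adjusted p = 0.335) and on averaging its probe sets (adjusted p = 0.258), and that of ERAP2 ended without control 1, 4 or 5 or castration 1, 2, 4 or 5 (adjusted p from 0.0557 to 0.0911) and after quantile normalization (adjusted p = 0.0758). ERAP1 (0.55, adjusted p = 0.0673) passed without control 3 (adjusted p = 0.0134) or castration 3 (adjusted p = 0.046), and TAP2 (-0.38, adjusted p = 0.133) without control 1 (adjusted p = 0.0116).

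Among markers of host cells the fibroblast matrix genes rose. Of 10 measured, 6 rose, none fell and 4 did not pass (median 0.61, camera adjusted p = 0.0175, adjusted p = 0.396 with an estimated correlation). COL1A2 rose from 370 ± 215 to 1344 ± 665 (SD, n = 5 per group, 3.74-fold), COL3A1 2.94-fold, COL6A2 1.94-fold and COL6A1 1.73-fold, with adjusted p from 0.000516 to 0.00652, and COL1A1 (0.60) and COL5A2 (0.61), named outside the rule, rose as well. Averaging probe sets ended the calls of COL6A1 (adjusted p = 0.17) and COL3A1 (adjusted p = 0.571). No member of the endothelial (5 measured, median 0.03, camera adjusted p = 0.954), macrophage and granulocyte (4, median 0.22, adjusted p = 0.707), lymphocyte (4, median 0.07, adjusted p = 0.888) or adipocyte list (4, median 0.02, adjusted p = 0.992) passed. Camera, which compares with the other genes, pointed down for the endothelial and adipocyte lists. Their medians were positive but lay below the median of all genes tested (0.0455). CYBB of the macrophage list had a change of 0.58 (adjusted p = 0.0723) and passed without castration 4 (0.79, adjusted p = 0.0043). The others named by the rule were ENG (-0.19), ROBO4 (0.18), EGFL7 (0.13) and PECAM1 (-0.11) of endothelium, FCER1G (0.48), ITGAM (-0.03) and AIF1 (-0.03) of macrophages and granulocytes, CD3E (0.61), PRF1 (0.14), CD79A (-0.00358) and CD2 (-0.000281) of lymphocytes, and CFD (0.16), PPARG (-0.07), CIDEC (0.03) and LPL (0.00908) of fat. Among 8 muscle genes smooth muscle actin (ACTA2) fell 7.05-fold, from 4261 ± 3055 to 484 ± 120 (adjusted p = 0.000504), myoglobin (MB) rose 1.52-fold and 6 did not pass (median 0.09, mean -0.16, camera adjusted p = 0.954). The call of MB ended without castration 1 (adjusted p = 0.0501) or castration 2 (adjusted p = 0.052), while ACTG2 (0.64, adjusted p = 0.0557) passed without control 5 (adjusted p = 0.013) and TTN (0.40, adjusted p = 0.182) without castration 4 (adjusted p = 0.0486). The 2 measured erythroid genes, too few for a list test, did not pass: HBB (0.12, adjusted p = 0.505) and ALAS2 (-0.28, adjusted p = 0.361).

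**Figure D2:**
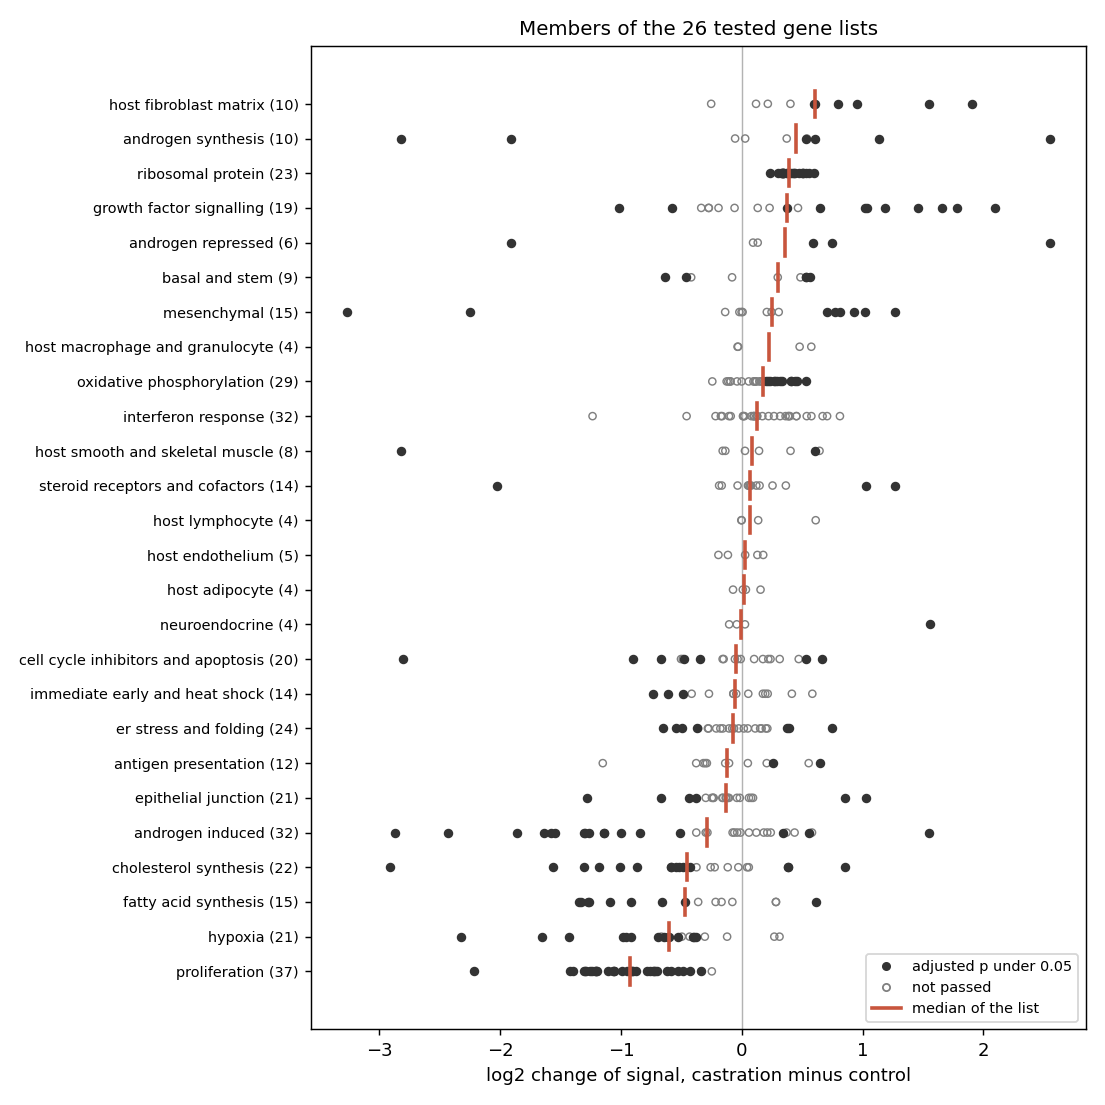
Log2 change of signal (castration minus control) of each measured member of the 26 tested lists, with the number measured in parentheses. Filled points passed at an adjusted p under 0.05, open points did not, and the orange-red bars are list medians, from -0.93 for proliferation to 0.61 for fibroblast matrix.

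Of the 26 lists tested, 8 passed with camera, 3 higher and 5 lower after castration. None passed with an estimated correlation, where the lowest adjusted p was 0.293, while 11 passed with fry and 10 by the permutation of the scores with Benjamini-Hochberg adjustment. With fry the androgen-repressed, androgen synthesis and growth factor lists passed besides those 8, and by the permutation the androgen-repressed and growth factor lists.

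**Figure D3:**
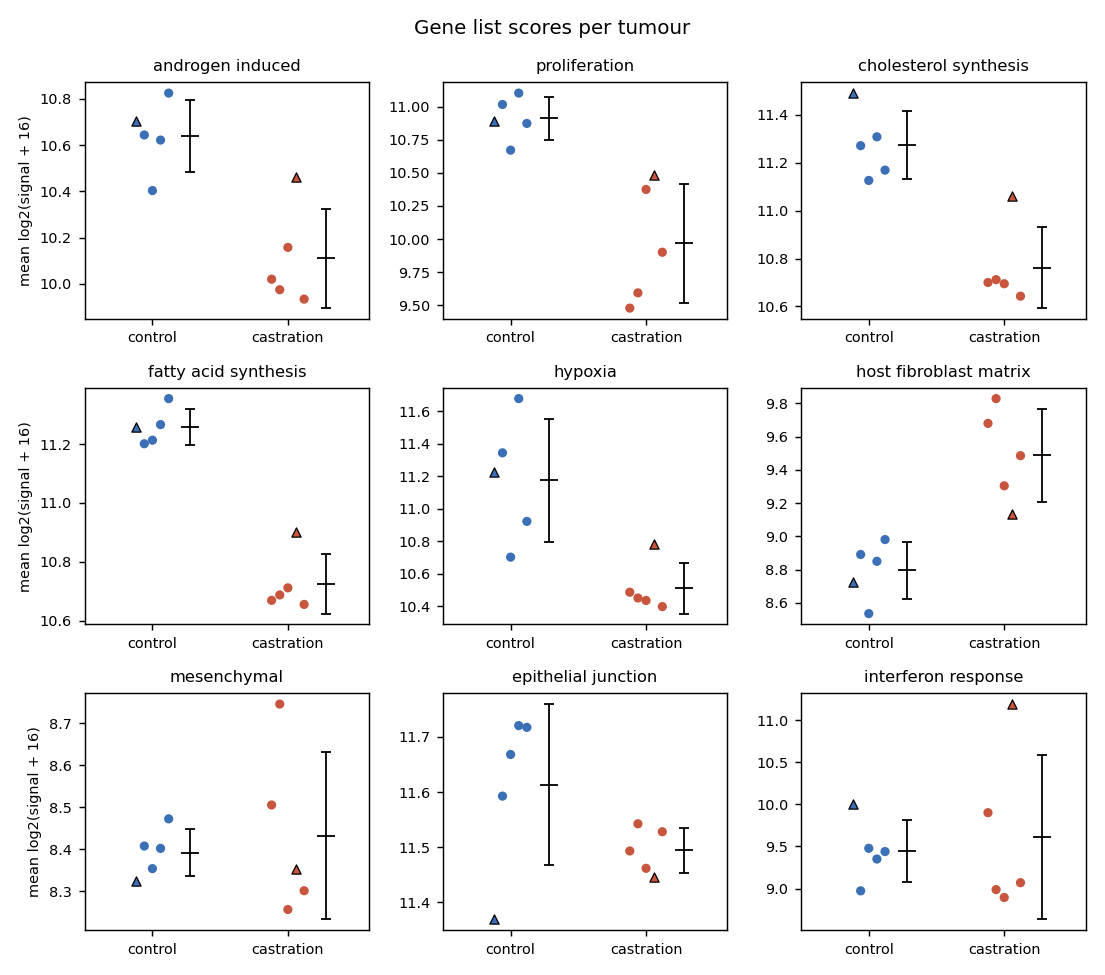
Mean log2(signal + 16) of 9 lists in each tumour, with controls in blue, castration in red, group mean and SD in black, and control 1 and castration 4 as triangles. The proliferation, cholesterol, fatty acid and fibroblast matrix scores did not overlap between the groups, while the interferon score was highest in castration 4 (11.2).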

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

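The mixing tests, the splits of the samples and the test of the matrix list without 1 tumour were set before their results were seen, and the other tests of explanations were chosen after. The rule for reading the mixing tests was made stricter after their values were seen: an interval must lie wholly beyond a difference of 0.1 to exclude mixing. A rise of the ribosomal protein genes was tested at first in the place of the pattern of control 1 and castration 4, and its values are given at the end. Of 336 groups of 5 values examined, 38 held a tumour far from the others, where chance gives about 1 in 20 for independent normal values. These groups come from the same tumours, share genes with the lists and include genes chosen by their results. The 38 can therefore not be read as an excess over chance. Castration 4 was that tumour in 12 of the 38 and control 1 in 10, against 5 for control 3, 4 for control 4, 3 for control 5, 2 for control 2 and 1 each for castration 1 and castration 3.

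Castration 4 stood above the other castration tumours in MYBPC1 (798), NDRG1 (10379), HSD17B6 (2127), PGK1 (11221), BST2 (12108) and EGFL7 (1041), and in the scores of cholesterol synthesis (11.1), fatty acid synthesis (10.9), protein folding (11.7), hypoxia (10.8) and steroid receptors (10.9). Control 1 stood below the other controls in LEFTY1 (641), S100P (1179), LOC283352 (2761), RBM20 (113), ESRP2 (1406) and TAP2 (357), and above them in SI (82.6), RAB25 (3190), ESR1 (449) and FGFR2 (286). In TAP2 the log2 change was -0.54 without control 1 (adjusted p = 0.0116).

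Other tumours stood apart in fewer genes and lists. Control 3 was low in UQCRB (12352), NDUFB5 (5440) and RPS9 (15688). Control 4 was high in DEFB1 (1707) and low in PECAM1 (304), CD3E (41.6) and the lymphocyte score (7.47). Control 5 was low in AKR1C3 (42.8) and high in TCF4 (992) and ROBO4 (172). Control 2 was low in HSD17B4 (4100) and ACACA (2541), castration 1 was high in F3 (1315) and castration 3 was low in JUNB (455). Among 4472 probe sets above the filter with several gene symbols or none, which the comparison of genes did not use, 759 changed, 524 higher and 235 lower after castration.

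Control 1 and castration 4 lay between the groups in the principal components. A swap of their labels is argued against, since both correlated better with their own group than with the other, by at least 0.0121 in mean r. Mixing with RNA of the other group would give 1 share from genes that rose and from genes that fell, taken from the 8 other tumours. In control 1 the shares were 22.7% and 39.9%, a difference of -0.172 (95% bootstrap interval over genes -0.233 to -0.102, whose near end only just clears that bound). By the rule this would exclude a single share. However, the interval treats the genes of 1 array as independent and leaves out the spread between tumours. No tumour known to be unmixed was put through the same calculation, so mixing in control 1 is not excluded. In castration 4 the difference was 0.115 (interval 0.0532 to 0.162), and the shares were 0.384 (interval 0.334 to 0.425) and 0.270 (interval 0.242 to 0.302). The rule written before, a difference over 0.1 with shares whose intervals do not overlap, would have excluded mixing in castration 4, and the stricter rule would not. The same limits of the interval hold there, so mixing stays open in both tumours. The 3-prime to 5-prime ratio of both tumours (2 of 2) lay inside the range of the others of their group, which argues against RNA degradation. A weaker response to castration in castration 4 stays open, and no biological explanation was tested for either tumour, since the design names none.

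Of the androgen-induced genes, 18 of 32 did not fall. Saturated probe sets stay open: 16 of the 18 had a lower control signal than NDRG1 (18997), which fell, but probe sets differ in the signal at which they saturate, so this level decides nothing. An earlier test, the difference of the median log2 level between members that did not fall and that did (0.181, permutation p = 0.894), had decided nothing either, and probe sets that respond weakly stay open. Spread between tumours hiding a halving is argued against for the chosen probe sets of all 18, whose 95% intervals lay above a log2 change of -1. Their other probe sets are not covered by this. In limma 1 of MED28 had a log2 change of -1.29 (adjusted p = 0.0126) and another of -0.42 (adjusted p = 0.0491). The choice of probe set cannot be told apart from a lack of response: of 32 other probe sets of these genes 7 fell (21.9%), all in ABCC4, TPD52 and MED28, named after their values were seen, and 1 rose. Some of these genes may thus have fallen through another probe set, and androgen made outside the testes or a response spared by castration was not tested.

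The rise of the fibroblast matrix genes did not rest on 1 tumour, since the list passed without any of the 10 (highest adjusted p = 0.0332). More host RNA of every cell type could also raise them. The markers of host endothelium, macrophages, lymphocytes and fat, 17 of 56 measured, had a median change of 0.0284 (from -0.19 to 0.61), below that of the matrix genes by 0.58 (permutation p = 0.00162), but their median level (8.08) was too close to the filter (7.05) to decide. The muscle and erythroid lists were left out of this test; in them ACTA2 fell by 2.82 on the log2 scale and ALAS2 had a change of -0.28, and the muscle list had a median of 0.09. Matrix genes made by the human tumour cells were not tested.

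For the ribosomal protein genes, the median change of 0.40 lay above that of 10000 random lists drawn within 20 bins of brightness (highest 0.359, 95th percentile 0.252). Such lists match brightness only by bin, and the ribosomal genes were among the brightest. They also leave out the correlation between members, estimated at 0.74 for this list. The 7 genes on probe sets without a cross-hybridisation suffix had a median of 0.44, with 7 of 7 higher. The oxidative phosphorylation median lay at percentile 87.0 of such lists.

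The count of 4084 changed genes can be set against other groupings of the same tumours: of 100 splits drawn from 126, 1 gave as many genes, the real split itself. A share of 1 in 100 is the smallest that these splits can give, so chance is made unlikely but is not excluded. The splits cannot address a factor other than castration that differed between the groups. The highest other split gave 1128 genes and exchanged control 1 and castration 4.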

How the results depend on the processing

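Alternatives were planned before the data were examined, except leaving out control 1 and castration 4 together, the Welch calculation on unlogged signals and the repeat with probe sets kept, which were chosen after seeing the data. The 4084 changed genes became 6691 when every probe set was tested by itself (3194 lower), 2218 at an adjusted p under 0.01, 702 at a change of at least 2-fold, 2722 with a Welch calculation on unlogged signals (1057 lower) and 2873 with one on log2 values (1142 lower, 2782 shared with the 4084). Quantile normalization gave 3993, of which 3757 were shared, and the 8 tumours without control 1 and castration 4 gave 4806, of which 3847 were shared. Leaving out 1 tumour gave 3141 to 4471 genes. Of the 4084 genes 2349 were higher and 1735 lower, against 2095 and 1963 with arrays centred on their median, 2175 and 1818 after quantile normalization and 1687 and 1594 with averaged probe sets. The 8 lists became 0 with an estimated correlation. The mesenchymal score (0.04) was 0.92 with the filter at the 75th percentile (exact permutation p = 0.0238). That filter left fewer than 3 measured members, too few for a list test, so this value does not describe the list as a whole. The score reversed to -0.525 with averaged probe sets, while the list median stayed positive in every setting that tested the list (lowest 0.0978). Without 1 tumour the score ran from -0.158, reversed without castration 2, to 0.0729. The settings that left out tumours or changed the offset chose the probe set of a gene again. This exchanged that of LOX without castration 1, 2, 3 or 4, without control 1 and castration 4, and at an offset of 64. With the probe sets of all 10 arrays kept, chosen after seeing this, the mesenchymal score ran from -0.0380 to 0.0841 without 1 tumour and no exact permutation p was under 0.05. Without castration 2 the score stayed negative (-0.0380, exact permutation p = 0.508). The passing p of that setting, and not its sign, thus came with the exchange. With probe sets kept, 3143 to 4480 genes changed without 1 tumour, and of the calls of named genes only that of HOXB13 at an offset of 64 differed (adjusted p = 0.0502 against 0.0499). The epithelial score (-0.12) was -0.181 at the 75th percentile, -0.196 with averaged probe sets and -0.168 without control 1 and castration 4, and ran from -0.180 to -0.0926 without 1 tumour. The cause of these changes was not tested, other than fewer genes at stricter thresholds. The androgen-induced and proliferation scores kept their direction and side of the threshold under all alternatives run. Apart from the estimated correlation, which ended all 8, the alternatives ended the call of 1 list of 8, oxidative phosphorylation (0.0967 after quantile normalization). Of 106 changed named genes 71 passed in every one of 21 settings that measured them, 35 were lost under at least 1, and of 36 others 10 passed under at least 1; none reversed. Averaging probe sets moved some folds by over 1.5 times without ending the call: FKBP5 11.02-fold, LAMA1 10.6-fold, JAG1 5.33-fold, PTPRB 4.00-fold, LOX 9.13-fold, ANKRD37 1.66-fold, ELOVL5 1.43-fold and IDI1 1.51-fold. An offset of 64 did so for F3 (10.3-fold), GIMAP7 (7.07-fold), SI (6.62-fold), DEFB1 (5.58-fold) and CDKN1A (4.59-fold), and no offset for F3 (30.1-fold) and GIMAP7 (29.5-fold). Leaving out both control 1 and castration 4 did so for LEFTY1 (42.1-fold), MYBPC1 (38.6-fold), S100P (30.6-fold), GIMAP7 (20.6-fold) and HSD17B6 (6.00-fold). A Welch calculation on log2 values ended 23 gene calls, among them GIMAP7 (adjusted p = 0.0612), SNAI2 (0.0788), STEAP2 (0.0749), HSD17B6 (0.0894), COL3A1 (0.0502), IRS2 (0.0713), GATA2 (0.0557), KRT8 (0.0549), BMI1 (0.0622) and HYOU1 (0.0731). A filter on detection calls, a second table of values per sample and a block for scan date were not run, since the files used here do not hold them. No paired analysis was possible because the labels give no replicate numbers. Signals near background limit what can be seen in dim genes such as CDH2 and ZEB1.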

Other observations

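The gene families described here were tested after the data were seen, as 398 groups of genes sharing the start of their symbol, and the genes named in them lie outside the naming rule and were chosen after their values were seen. Of the families 8 passed with camera (each with an adjusted p = 0.927 with an estimated correlation). For comparison, 2349 of all 12940 genes tested rose and 1735 fell. MCM6, ELOVL5 and ELOVL6 are also members of the proliferation or fatty acid list, so some of these families repeat results given above. Besides ribosomal proteins, the genes named MCM, which include those of the replicative helicase, fell: 8 of 9 measured (median -0.70, camera adjusted p = 0.0013), with MCM4 from 5076 ± 855 to 2531 ± 876 (SD, n = 5 per group). Genes named CDC fell in 11 of 21 and rose in 1 (median -0.43, adjusted p = 0.0174), among them the phosphatase gene CDC25B (-1.24 ± 0.16 SE). The elongases of very long fatty acids fell in 4 of 5 (median -1.27, adjusted p = 0.00529), with ELOVL2 from 6112 ± 1038 to 1447 ± 306. Genes named PSMD, which include subunits of the proteasome lid and base, fell in 7 of 14 and rose in 1 (median -0.34, adjusted p = 0.0174), among them PSMD11 (-0.60 ± 0.12). Mitochondrial ribosomal proteins of the large subunit fell in 11 of 48 and rose in 2 (median -0.17, adjusted p = 0.0163), among them MRPL34 (-0.50 ± 0.11).

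Zinc finger genes named ZNF rose in 94 of 367 and fell in 13 (median 0.20, camera adjusted p = 0.00877), among them ZNF680, from 1030 ± 244 to 2988 ± 860 (SD, n = 5 per group), and ZNF362 (1.21 ± 0.15 SE). Cytosolic ribosomal proteins rose in 40 of 45 RPL genes (median 0.38) and 27 of 29 RPS genes (median 0.36), and 1 RPL gene fell. Other scalings were run for the ribosomal list, whose rise depended on them, and not for these families.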
